A study of Mus musculus with 9 samples.

How the data were processed

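RNA was sequenced from ST2 cells, a stromal cell line established from mouse bone marrow culture. The cells had been fed human neutrophils that had been frozen for at least 18 h and stained with a membrane dye at 20 µM, at 10 neutrophils per ST2 cell, once the ST2 cells were about 80% confluent. Per the labels' protocols, fed cells were sorted by flow cytometry for a dye signal equal to at least a whole neutrophil, after 3 h or 24 h of feeding. The 9 libraries formed 3 groups of 3: unfed ST2 cells collected at 24 h, ST2 cells positive for neutrophil uptake at 3 h and ST2 cells positive for uptake at 24 h. There were no unfed libraries at 3 h. The labels number the replicates but do not state that they were separate cultures, so every p-value measures only the spread between these libraries.

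The deposited table held raw read counts per mouse gene symbol, with 1 column per library, no normalization and no pooling. Per the submitters' processing notes, the tools were STAR 2.7.0f, Subread 1.6.4 with featureCounts, and MultiQC 1.7, and the genome builds were GRCm38.p6 (mouse) and GRCh38.p13 (human). The annotation release, the strand setting, the treatment of reads that map to several places and the way in which the 2 genomes were used are not given in the sources used here. The protocols differ on the library kit. The sample protocol gives 50 ng of total RNA and a stranded mRNA kit (TruSeq), whereas the series text gives 1 ng of RNA, cDNA amplified with SMART-Seq v4 and 150 pg of cDNA in a Nextera XT library. Whether the reads kept their strand is therefore unresolved, and counts of genes that overlap another gene, or that share sequence with a near-identical copy, are uncertain.

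The table had 55453 lines, of which 54484 (98.3%) carried a symbol of the mouse annotation GENCODE M21. In 26 lines the symbol had been turned into a date, as spreadsheet programs do, and 2 lines repeated a symbol. The table contained 0 lines of human genes, so the share of human reads could not be computed. Of the 13 protein-coding mitochondrial genes, 7 had counts and 6 had at most 1 count in any library, so the mitochondrial list covers only the former. Total counts ran from 44442664 to 55971275 per library. Between replicates of a group, the spread over genes was 5.47 to 16.1 times that of counting alone (chi-square per degree of freedom), over all genes together. Intervals and limits from counts cover counting error only, since PCR copies could not be removed.

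Genes were tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with TMM factors (trimmed mean of M values) and the filterByExpr filter, which kept 13568 genes holding at least 99.96% of the counts of each library. All 9 libraries entered a single fit with the group as the only term, and the common biological coefficient of variation was 0.0536. P-values were adjusted by the Benjamini-Hochberg method over the 13568 genes, and a gene was called at an adjusted p under 0.05. Expression levels are given as CPM, counts relative to the total of the library scaled by the TMM factors, as mean ± SD of 3 libraries, and fold changes on the log2 scale with their standard error (SE). Coordinates are those of GRCm38 in GENCODE M21.

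The design, the gene lists, the rule for named genes and most of the alternatives were chosen before the data were examined. The rule named, in each comparison, the 8 genes with the largest rise and the 8 with the largest fall among called genes whose 3 libraries of one group all lay above the 3 of the other, with a mean of at least 10 CPM in the higher group. Ribosomal protein genes, haemoglobins, pseudogenes and uncharacterised clones were left out of it. It also named up to 3 called members per direction of each list described, with a mean of at least 5 CPM, and a fixed set of osteoblast, niche, engulfment and mitochondrial genes. Not every gene that the rule names is described.

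In all, 33 lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2), at a preset correlation between genes of 0.01, with adjustment over the lists of each comparison. Camera compares the members of a list with all other tested genes. It was run again with the correlation estimated from the data for each list, and fry, which asks whether the members move in a common direction, was run on the same values. The lists covered osteoblast, adipocyte and chondrocyte genes, haematopoietic niche factors, engulfment, lysosome, autophagy, mitochondrial functions, stress responses, glycolysis, hypoxia, inflammation, interferon, sterol and fatty acid metabolism, cell cycle, p53 targets, immediate early genes, heat shock, matrix, contractile genes, apoptosis, and markers of neutrophils, macrophages and endothelial cells. Lists of erythroid and platelet markers and of lymphocyte markers had 2 and 0 tested members and received no test. A further 7 lists were added after the data were seen.

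The alternatives were DESeq2 size factors, the Wald test of DESeq2 1.42.0, limma-voom with sample quality weights, no filter or a stricter filter on low counts, the replicate number as a term of the model, a fit of only the 6 libraries compared, a minimum log2 fold change of 1, and leaving out mitochondrially encoded genes or each library in turn. A fit without 2 rows known to collect ribosomal RNA reads (Gm42418 and Gm26917) was added after the data were seen. The overlap of calls between the comparisons with unfed cells was set against 20 simulations in which all groups had the means of the unfed cells.

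The procedure was tested on simulated data with 200 of the 13568 genes changed. At a true fold of 1.2 it recovered 38.0% of the changed genes in the comparison of fed 24 h with unfed cells, 50.0% in that of fed 3 h with unfed cells and 44.0% in that of fed 24 h with fed 3 h cells. At a fold of 1.5 the shares were 71.0%, 73.0% and 77.0%. False calls made up 7.63%, 5.39% and 5.47% of the calls, the raised list was recovered each time and 0 other lists were called. Each comparison had a single simulation, and genes were drawn independently of one another. The list result therefore cannot show how camera behaves where the members of a list are correlated. The changed genes were also a far smaller share than the 30.8% to 60.9% called in the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.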

Results

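Gene expression was measured by RNA sequencing in ST2 cells, a mouse bone marrow stromal cell line that can form osteoblasts, left unfed or sorted for uptake of human neutrophils near the end of their life. The clearing of dying cells by engulfment is called efferocytosis, and the title of the series ties it to osteoblastic differentiation and to the remodelling of mitochondria. The 3 groups of 3 libraries were unfed cells collected at 24 h, cells sorted for uptake after 3 h of feeding (fed 3 h) and cells sorted for uptake after 24 h (fed 24 h). Total counts were 45709336, 48736073 and 44442664 in the unfed libraries, 49525932, 46322396 and 51205019 in the fed 3 h libraries and 49387906, 55971275 and 52013440 in the fed 24 h libraries. The first principal component of log2 CPM held 62.3% of the variance and the second 10.8%. On the first, the fed 3 h libraries lay on one side and the unfed and fed 24 h libraries on the other. Mitochondrially encoded genes took 1.56 ± 0.0711% of the counts in unfed, 1.40 ± 0.248% in fed 3 h and 1.95 ± 0.233% in fed 24 h libraries (SD, n = 3 each). Genes that collect ribosomal RNA reads (Gm42418 and Gm26917), a sign of RNA or library quality, took 0.102 ± 0.0125%, 0.149 ± 0.0865% and 0.298 ± 0.0838%. The mitochondrial shares leave out 6 of the 13 mitochondrial mRNAs, which had at most 1 count in any library.

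Cells fed for 24 h were compared with unfed cells of the same time, the comparison matched in time, which asks what cells that had taken up neutrophils expressed differently. The fed cells were only the fraction sorted for uptake. Feeding and the selection of these cells therefore differed together and cannot be told apart. Immediate early genes, which are switched on within minutes of a stimulus, showed the largest rises among the named genes. Fos, a subunit of the transcription factor AP-1 (chromosome 12, 85473890 to 85477273), rose from 26.3 ± 4.94 to 304 ± 51.2 CPM (SD, n = 3 each), a log2 fold change of 3.53 (SE 0.261, edgeR adjusted p = 1.54e-06). Its relative Fosb (chromosome 7, 19302696 to 19310051) rose by 4.19 (SE 0.400), from 3.19 ± 0.860 to 58.6 ± 5.72 CPM. Of the haematopoietic niche factors, 11 of 17 rose, a list call that was lost with an estimated correlation (adjusted p = 0.465). In fits of the 6 libraries compared, camera called 11 lists at 24 h, but up to 14 when fed and unfed libraries were mixed. Rises and falls of lists at 24 h are therefore descriptions of their members, not secure list calls. Cxcl12, the chemokine that retains blood stem cells in the marrow (chromosome 6, 117168535 to 117181367), rose from 5712 ± 783 to 7974 ± 285 CPM (log2 0.48, SE 0.0728). The largest fall among the named genes was that of Has2, a hyaluronan synthase (chromosome 15, 56665627 to 56694539), from 17.1 ± 0.384 to 8.29 ± 0.616 CPM (log2 −1.04, SE 0.0968, edgeR adjusted p = 5.93e-06).

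Of 13568 genes, 2017 were higher and 2159 lower in fed 24 h cells by the edgeR test. Most changes were small. The median absolute log2 fold change of the called genes was 0.26, and 103 higher and 47 lower genes reached a log2 fold change of 1. In 43.2% of the genes the 3 libraries of one group all lay above those of the other, where chance gives 10%. The other largest rises among the named genes were in Cxcl1, a chemokine that attracts neutrophils (2.00), Ppp1r15a, a phosphatase subunit that ends the integrated stress response (1.62), Clec2d, a lectin-like ligand of natural killer cell receptors (1.55), Dusp1, a phosphatase of MAP kinases (1.54), Nr4a1, an early-induced nuclear receptor (1.54), and Sparcl1, a matricellular protein (1.53). Other large falls were in Kcnf1, a potassium channel subunit (−0.73), Ccn4, a WNT-induced matricellular protein (−0.73), Pik3cb, a PI3-kinase subunit (−0.69), Ranbp6, of the importin family (−0.68), Hmga1b (−0.68) and Cdca7, a cell cycle gene (−0.67). Hmga1b has a near-identical copy, Hmga1, so its count is uncertain. Without fed 24 h replicate 1, 1426 genes were lower.

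Osteoblast genes moved both ways. Runx2, the master regulator of the osteoblast lineage (chromosome 17, 44495987 to 44814797), rose from 69.6 ± 1.58 to 82.3 ± 4.80 CPM (log2 0.24, SE 0.0559, edgeR adjusted p = 0.00443). Spp1, which encodes the bone matrix protein osteopontin (chromosome 5, 104435118 to 104441050), rose by 0.63 (SE 0.0557), from 2279 ± 139 to 3525 ± 174 CPM. Alpl, the alkaline phosphatase needed for mineralization (chromosome 4, 137741733 to 137796384), rose by 0.34 (SE 0.0798). Sp7, a regulator downstream of Runx2, rose by 0.73 (SE 0.232) at a low level of 1.31 ± 0.273 CPM. This call ended without unfed replicate 2 or 3 or fed 24 h replicate 1 or 2, with values from 0.58 to 0.74. Col1a1, the main collagen of bone, was not called (−0.05, adjusted p = 0.461), and Tnfrsf11b, which encodes the osteoclast inhibitor osteoprotegerin, fell by 0.40. Bglap, which encodes osteocalcin, had 1, 2 and 2 counts in all unfed, fed 3 h and fed 24 h libraries, and Bglap2 had 5, 0 and 9. A difference was not detectable at such counts, and how reads that map to several places were treated is not known. The osteoblast list had 10 of 22 higher and 5 lower (the same numbers adjusted over the list alone). Its median was 0.12, and the list was not called (camera adjusted p = 0.207, adjusted p = 0.616 with an estimated correlation).

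The niche factors had 11 of 17 higher and 0 lower (the same numbers adjusted over the list alone), with a median of 0.29 (camera adjusted p = 0.000237, adjusted p = 0.465 with an estimated correlation). Kitl, the stem cell factor (chromosome 10, 100015630 to 100100416), rose from 412 ± 56.6 to 521 ± 14.3 CPM (log2 0.34), and Foxc1, a transcription factor of niche cells, by 0.34. Immediate early genes had 18 of 28 higher and 4 lower (20 and 4 adjusted over the list alone). Their median was 0.61 (camera adjusted p = 1.45e-05, adjusted p = 0.465 with an estimated correlation). The members that fell included the transcription factors Klf10 (−0.52), Fosl1 (−0.31) and Srf (−0.25). Interferon-stimulated genes had 14 of 31 higher and 1 lower (17 and 1 adjusted over the list alone). Their median was 0.36 (camera adjusted p = 5.72e-05, adjusted p = 0.536 with an estimated correlation). Among them were Bst2, which tethers budding virus particles (0.75), and Psmb9, a subunit of the immunoproteasome (0.47).

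Lysosomal genes rose, 15 of 36 higher and 0 lower (18 and 0 adjusted over the list alone). Their median was 0.12 (camera adjusted p = 0.000221, adjusted p = 0.536 with an estimated correlation). Ctsk, a protease that degrades collagen, rose by 0.52, Psap, the precursor of activators of lipid breakdown, by 0.36 and Mcoln1, a lysosomal calcium channel, by 0.28. Engulfment genes had 10 of 25 higher and 5 lower (10 and 8 adjusted over the list alone). Their median was 0.09, and the list was not called (camera adjusted p = 0.207, adjusted p = 0.536 with an estimated correlation). Gas6, the ligand that bridges dying cells to the receptors Tyro3, Axl and Mertk (chromosome 8, 13465374 to 13494490), rose from 128 ± 19.2 to 202 ± 11.1 CPM (log2 0.65, SE 0.0775). Axl fell by 0.19 (SE 0.0541), from 945 ± 56.5 to 827 ± 43.0 CPM, a call that ended without unfed replicate 2 or fed 24 h replicate 1 or 3 (values −0.18 to −0.14). Mertk was near the floor, with 57 counts in all unfed and 105 in all fed 24 h libraries (0.69, adjusted p = 0.132). Tyro3 was not called (−0.16, adjusted p = 0.0578), but it was called without unfed replicate 1 (−0.20) or fed 24 h replicate 2 (−0.21) and by limma-voom (−0.20). Autophagy genes had 6 of 27 higher and 1 lower (the same numbers adjusted over the list alone) and were not called (median 0.03, camera adjusted p = 0.407, adjusted p = 0.622 with an estimated correlation).

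Mitochondrial lists moved in different directions at 24 h. The testable mitochondrially encoded mRNAs had 6 of 7 higher and 0 lower (the same numbers adjusted over the list alone). Their median was 0.35 (camera adjusted p = 0.0214, adjusted p = 0.536 with an estimated correlation), a call that ended without unfed replicate 1 or 2 or fed 24 h replicate 2 (adjusted p from 0.00148 to 0.0899 over the alternatives). mt-Nd5, a subunit of complex I, rose from 1083 ± 22.8 to 1556 ± 117 CPM (log2 0.52). The fed 24 h libraries also had the highest mean shares of mitochondrial and of ribosomal RNA linked reads. Regulators of mitochondrial biogenesis fell, 6 of 18 lower and 0 higher (9 and 0 adjusted over the list alone). Their median was −0.15 (camera adjusted p = 0.000470, adjusted p = 0.536 with an estimated correlation). Pprc1, a coactivator of the PGC-1 family, changed by −0.55, Twnk, the mitochondrial DNA helicase, by −0.33 and Tfam, which packages mitochondrial DNA (chromosome 10, 71225464 to 71238280), by −0.26. Ppargc1a had 1 count in the unfed and 0 in the fed 24 h libraries, so a difference was not detectable at this depth. Nuclear genes of oxidative phosphorylation had 6 of 71 higher and 3 lower (2 and 2 adjusted over the list alone) and were not called (median 0.02, camera adjusted p = 0.703, adjusted p = 0.959 with an estimated correlation). Fission and fusion genes had 1 of 24 higher and 9 lower (the same numbers adjusted over the list alone) and were not called (median −0.03, camera adjusted p = 0.117, adjusted p = 0.536 with an estimated correlation). Mief1, a receptor for the fission protein DRP1, changed by −0.35 and the prohibitin Phb2 by −0.25. Opa1, which fuses inner membranes, rose by 0.14, but the call ended without fed 24 h replicate 1 or 3 (values 0.12 to 0.13). The fusion gene Mfn2 fell by 0.11, a call that ended without unfed replicate 2 or 3, any fed 3 h replicate or fed 24 h replicate 1 or 3 (values −0.12 to −0.09). It also ended with DESeq2 size factors, with no filter or a stricter filter, with the replicate number in the model, in the fit of 6 libraries and without the genes linked to ribosomal RNA (adjusted p from 0.0179 to 0.173 over the alternatives). Mfn1, its paralog (−0.04, adjusted p = 0.572), and Dnm1l, which encodes DRP1 (0.08, adjusted p = 0.144), were not called, but Dnm1l was with the stricter filter (0.09, adjusted p = 0.0477, to 0.364 over the alternatives).

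The mitophagy list rose weakly, 6 of 17 higher and 2 lower (7 and 2 adjusted over the list alone). Its median was 0.06 (camera adjusted p = 0.0467, adjusted p = 0.465 with an estimated correlation). The call ended with the replicate number in the model and without unfed replicate 1 or 2, fed 3 h replicate 2 or 3 or fed 24 h replicate 1 or 2 (adjusted p from 0.0273 to 0.0702 over the alternatives). Calcoco1, an autophagy receptor, rose by 0.51, Optn, a receptor for ubiquitinated mitochondria, by 0.44, and Pink1, the kinase that marks damaged mitochondria, from 24.2 ± 1.10 to 28.8 ± 0.979 CPM (log2 0.25). Genes of fatty acid oxidation had 9 of 25 higher and 0 lower (the same numbers adjusted over the list alone). Their median was 0.09 (camera adjusted p = 0.0214, adjusted p = 0.536 with an estimated correlation), and the call ended without unfed replicate 2 or 3 or fed 24 h replicate 2 (adjusted p from 0.00175 to 0.0883 over the alternatives). Acadm, the medium-chain acyl-CoA dehydrogenase, rose by 0.42. The list of the integrated stress response and the mitochondrial unfolded protein response fell, 12 of 23 lower and 3 higher (13 and 5 adjusted over the list alone). Its median was −0.16 (camera adjusted p = 0.00966, adjusted p = 0.536 with an estimated correlation). Psat1 (−0.54) and Shmt2 (−0.43), enzymes of serine metabolism, and Asns, asparagine synthetase (−0.44), were among the falls. Other members of the list were higher. Nupr1 ran from 40.35 to 46.1 CPM in fed 24 h and from 29.8 to 38.6 CPM in unfed libraries. Ddit3 ran from 13.3 to 15.9 CPM and from 11.5 to 12.3 CPM.

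Genes of DNA replication and S phase fell at 24 h, 16 of 30 lower and 0 higher (18 and 0 adjusted over the list alone). Their median was −0.14 (camera adjusted p = 7.17e-06, adjusted p = 0.536 with an estimated correlation). Ccne2, a cyclin of S phase entry, changed by −0.43, Cdc6, a loader of the replicative helicase, by −0.36 and Mcm7, a subunit of that helicase, by −0.34. G2 and mitosis genes had 5 of 30 higher and 4 lower (the same numbers adjusted over the list alone) and were not called (median −0.01, mean 0.01, camera adjusted p = 0.952, adjusted p = 0.984 with an estimated correlation). Contractile genes and targets of YAP or SRF fell, 10 of 21 lower and 2 higher (11 and 2 adjusted over the list alone). Their median was −0.13 (camera adjusted p = 0.00928, adjusted p = 0.616 with an estimated correlation). The call ended without unfed replicate 2 (adjusted p = 0.0663, from 0.000108 over the alternatives). Ankrd1 (−0.51) and Ccn2 (−0.49), targets of YAP, fell, whereas Ccn1, another YAP target, rose (0.46). Collagen and matrix genes rose, 15 of 34 higher and 1 lower (15 and 2 adjusted over the list alone). Their median was 0.11 (camera adjusted p = 0.00162, adjusted p = 0.536 with an estimated correlation), with the collagens Col16a1 (0.67), Col6a2 (0.54) and Col6a1 (0.47) among them.

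The other lists were not called at 24 h. Adipocyte genes had 5 of 18 higher and 2 lower (the same numbers adjusted over the list alone), with a median of 0.10 (camera adjusted p = 0.0942, adjusted p = 0.527 with an estimated correlation). Lpl, the lipoprotein lipase, rose by 0.70 and Fasn, fatty acid synthase, fell by 0.36. Chondrocyte genes had 1 of 6 higher and 1 lower (the same numbers adjusted over the list alone), with a median of 0.24 (camera adjusted p = 0.407, adjusted p = 0.622 with an estimated correlation). NF-kappaB inflammatory genes had 5 of 24 higher and 4 lower (7 and 4 adjusted over the list alone), with a median of 0.03 (camera adjusted p = 0.407, adjusted p = 0.693 with an estimated correlation). Mmp13, a collagenase in that list, rose by 1.22. Cholesterol genes had 1 of 24 higher and 4 lower (the same numbers adjusted over the list alone), with a median of −0.02 (camera adjusted p = 0.523, adjusted p = 0.844 with an estimated correlation). Liver X receptor targets had 4 of 13 higher and 0 lower (the same numbers adjusted over the list alone), with a median of 0.11 (camera adjusted p = 0.0685, adjusted p = 0.536 with an estimated correlation). This list was called without unfed replicate 1 (adjusted p = 0.0144) or fed 24 h replicate 3 (0.0385, to 0.116 over the alternatives). Hypoxia-inducible genes had 4 of 17 higher and 0 lower (3 and 0 adjusted over the list alone), with a median of 0.09 (camera adjusted p = 0.102, adjusted p = 0.527 with an estimated correlation). Glycolysis genes had 5 of 21 higher and 7 lower (5 and 10 adjusted over the list alone), with a median of −0.08 (camera adjusted p = 0.166, adjusted p = 0.704 with an estimated correlation). The glycolysis list was called lower without fed 24 h replicate 2 (adjusted p = 0.0474, to 0.385 over the alternatives). Oxidative stress genes had 1 of 21 higher and 6 lower (the same numbers adjusted over the list alone), with a median of −0.05 (camera adjusted p = 0.207, adjusted p = 0.536 with an estimated correlation). Osgin1, an oxidative stress response gene, rose 2.00-fold.

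Endoplasmic reticulum stress genes had 4 of 21 higher and 4 lower (4 and 5 adjusted over the list alone), with a median of 0.03 (camera adjusted p = 0.603, adjusted p = 0.732 with an estimated correlation). Cytosolic heat shock genes had 2 of 14 higher and 4 lower (2 and 5 adjusted over the list alone), with a median of −0.08 (camera adjusted p = 0.117, adjusted p = 0.536 with an estimated correlation). Hsph1, a chaperone of that list, fell by 0.36 and Cryab, a small heat shock protein, rose by 0.46. The p53 targets had 3 of 21 higher and 6 lower (4 and 6 adjusted over the list alone), with a median of 0.04, a mean of −0.01 and a downward test (camera adjusted p = 0.664, adjusted p = 0.832 with an estimated correlation). Apoptosis regulators had 2 of 21 higher and 2 lower (the same numbers adjusted over the list alone), with a median of −0.03 (camera adjusted p = 0.664, adjusted p = 0.754 with an estimated correlation). Bcl2, which blocks apoptosis, fell by 0.26, and its relative Mcl1 rose by 0.16. The markers of other cells were mouse genes, whereas the fed neutrophils were human. Low counts of neutrophil markers therefore cannot show how much neutrophil RNA the fed cells held. The 26 neutrophil markers together reached 4.76 ± 0.367 CPM in unfed, 4.25 ± 0.394 in fed 3 h and 6.33 ± 0.679 in fed 24 h cells. All fed 24 h libraries (5.66 to 7.02 CPM) lay above the unfed ones (4.34 to 5.00 CPM). The neutrophil list had 0 of 4 higher and 0 lower (the same numbers adjusted over the list alone), with a median of 0.39 (camera adjusted p = 0.207, adjusted p = 0.536 with an estimated correlation). S100a8 and S100a9, abundant transcripts of neutrophils, had 0, 2 and 1 counts together in all unfed, fed 3 h and fed 24 h libraries. Macrophage markers had 1 of 3 higher and 0 lower (the same numbers adjusted over the list alone), with a median of 0.48 (camera adjusted p = 0.407, adjusted p = 0.585 with an estimated correlation). Endothelial markers had 0 of 4 higher and 1 lower (the same numbers adjusted over the list alone), with a median of 0.05, a mean of −0.05 and a downward test (camera adjusted p = 0.631, adjusted p = 0.704 with an estimated correlation).

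**Figure D1:**
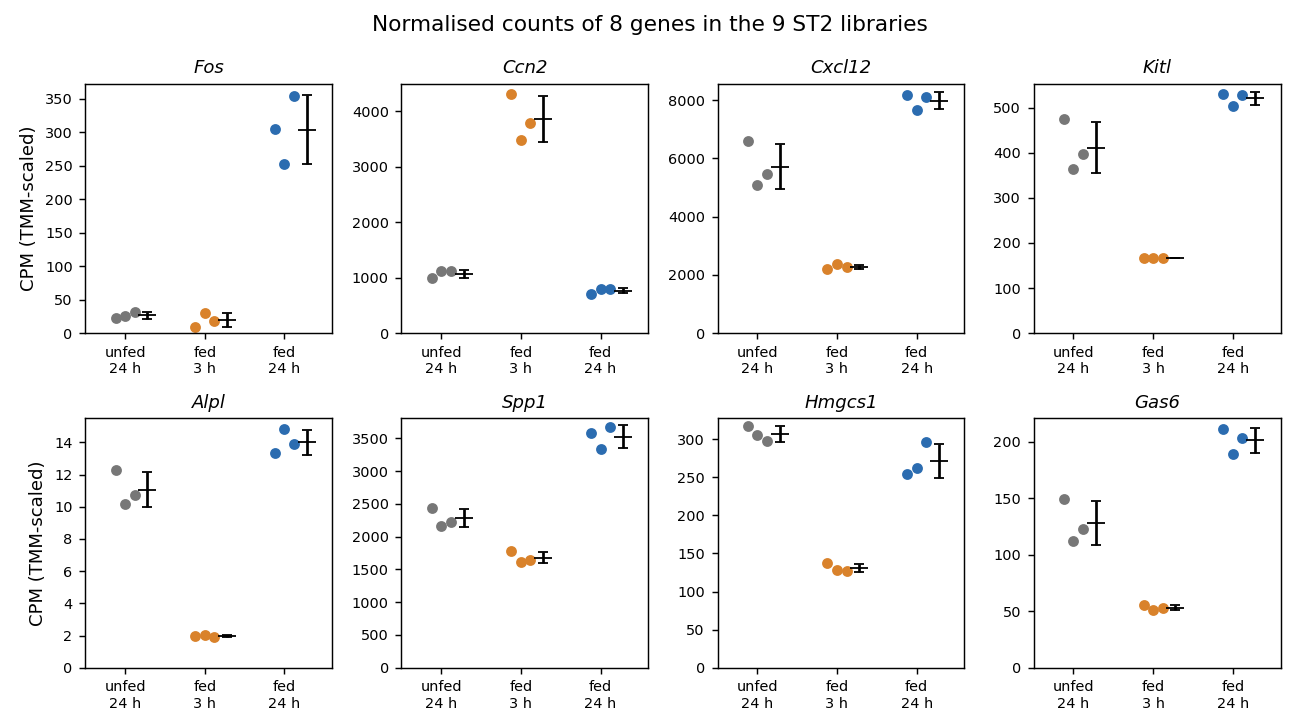
Expression in CPM scaled by TMM factors (vertical axes, linear, each starting at 0) of 8 genes in each of the 9 libraries, with the mean and SD of the 3 libraries of each group beside the points. Fos reached 304 ± 51.2 CPM in fed 24 h cells, Ccn2 3861 ± 421 CPM in fed 3 h cells, and Cxcl12, Kitl, Alpl, Spp1, Hmgcs1 and Gas6 had their lowest group mean in fed 3 h cells.

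Cells fed for 3 h were compared with the same unfed cells of 24 h, so that feeding, the selection for uptake and time in culture differed together. Ccn2, the connective tissue growth factor (chromosome 10, 24595442 to 24598683), rose from 1070 ± 72.7 to 3861 ± 421 CPM (SD, n = 3 each), a log2 fold change of 1.85 (SE 0.0743, edgeR adjusted p = 6.34e-11). All 24 tested genes of cholesterol synthesis and uptake were lower. Lss, which closes the sterol ring (chromosome 10, 76531588 to 76557138), fell from 139 ± 10.3 to 45.3 ± 1.38 CPM (log2 −1.62, SE 0.0578). Of the niche factors, 13 of 17 were lower and 2 higher, a list call that was lost with an estimated correlation (adjusted p = 0.232). Cxcl12 fell to 2275 ± 75.4 CPM (log2 −1.33, SE 0.0739) and Kitl to 167 ± 0.495 CPM (log2 −1.305, SE 0.0711). Alpl fell from 11.1 ± 1.09 to 1.99 ± 0.0751 CPM (log2 −2.48, SE 0.0995, edgeR adjusted p = 6.34e-11).

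By the edgeR test, 3408 genes were higher and 3460 lower in fed 3 h cells. Their median absolute log2 fold change was 0.33, and 305 and 410 reached a log2 fold change of 1. In 58.2% of the genes the libraries of the groups did not overlap, against 10% by chance. Other large rises were in Sema7a, a membrane-bound semaphorin (2.59), Adamts6, a matrix protease (4.33-fold), Tnc, the matrix glycoprotein tenascin C (1.95), Il1rl1 (1.94), Nipal1, a magnesium transporter (1.87), and Aif1l, an actin-binding protein (1.85). Il1rl1 encodes the receptor of interleukin 33, which is also called ST2 but is unrelated to the name of the cell line. The other largest falls among the named genes were in Crocc2, a protein related to rootletin (−3.66), Kctd12, a subunit of GABA-B receptors (−3.10), Hp, the haemoglobin-binding protein haptoglobin (−2.98), Islr, a stromal cell surface protein (−2.95), Mc5r, a melanocortin receptor (−2.62), Colec10, a collectin (−2.50), and Il1rn, the interleukin 1 receptor antagonist (4.71-fold).

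The cholesterol list had a median of −1.18, with 24 of 24 lower and 0 higher (the same numbers adjusted over the list alone) (camera adjusted p = 3.76e-17, adjusted p = 0.232 with an estimated correlation). Fdps, which makes farnesyl pyrophosphate (−1.86), and Nsdhl, an enzyme late in the pathway (−1.61), fell with Lss. Liver X receptor targets fell, 7 of 13 lower and 1 higher (the same numbers adjusted over the list alone). Their median was −0.42 (camera adjusted p = 0.0240, adjusted p = 0.724 with an estimated correlation). The desaturase Scd2 changed by −1.36, and Soat1, which esterifies cholesterol, rose by 0.45. Fatty acid oxidation fell, 17 of 25 lower and 1 higher (17 and 2 adjusted over the list alone). Its median was −0.23 (camera adjusted p = 0.00222, adjusted p = 0.724 with an estimated correlation), and Acadm changed by −0.72. Adipocyte genes fell, 13 of 18 lower and 3 higher (13 and 4 adjusted over the list alone). Their median was −0.43 (camera adjusted p = 0.0165, adjusted p = 0.232 with an estimated correlation). Cebpa, a regulator of adipogenesis, changed by −1.07, while Pparg, another regulator, rose by 0.46 and Klf5, a transcription factor, by 1.47.

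The niche factors had 13 of 17 lower and 2 higher (the same numbers adjusted over the list alone) and a median of −0.49 (camera adjusted p = 0.000985, adjusted p = 0.232 with an estimated correlation). Bmp4, a bone morphogenetic protein, changed by −2.16, whereas Csf1, the macrophage growth factor, rose by 0.46. The osteoblast list had 4 of 22 higher and 9 lower (the same numbers adjusted over the list alone) and was not called (median −0.07, camera adjusted p = 0.266, adjusted p = 0.797 with an estimated correlation). Runx2 (0.01, adjusted p = 0.903) and Col1a1 (0.08, adjusted p = 0.231) were not called, Spp1 fell by 0.44, and Sp7 fell 2.01-fold, to 0.392 ± 0.0980 CPM. Interferon-stimulated genes fell, 15 of 31 lower and 0 higher (the same numbers adjusted over the list alone). Their median was −0.34 (camera adjusted p = 0.00222, adjusted p = 0.797 with an estimated correlation). The RNA sensors Ifih1 (−0.79) and Ddx58 (−0.77) were among them. Endoplasmic reticulum stress genes fell, 16 of 21 lower and 3 higher (the same numbers adjusted over the list alone). Their median was −0.26 (camera adjusted p = 0.000985, adjusted p = 0.232 with an estimated correlation). The chaperone Hspa5 changed by −0.67 and Xbp1, a transcription factor of this response, by −0.79.

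Contractile genes and targets of YAP or SRF rose, 19 of 21 higher and 0 lower (the same numbers adjusted over the list alone). Their median was 0.55 (camera adjusted p = 1.59e-08, adjusted p = 0.700 with an estimated correlation). Ankrd1 rose by 1.24 and Tagln, the actin-binding protein transgelin, by 0.78. S phase genes rose, 18 of 30 higher and 0 lower (the same numbers adjusted over the list alone). Their median was 0.17 (camera adjusted p = 0.00193, adjusted p = 0.797 with an estimated correlation), and Ccne1, a cyclin of S phase entry, rose by 0.52. G2 and mitosis genes had 12 of 30 higher and 7 lower (the same numbers adjusted over the list alone) and were not called (median 0.06, camera adjusted p = 0.383, adjusted p = 0.829 with an estimated correlation). Mitochondrial biogenesis rose, 12 of 18 higher and 1 lower (14 and 1 adjusted over the list alone). Its median was 0.15 (camera adjusted p = 0.00184, adjusted p = 0.711 with an estimated correlation). Pprc1 rose by 0.44 and Tfam by 0.14, the latter call ending without unfed replicate 2 or fed 3 h replicate 2 or 3 (values 0.11 to 0.13) and with no filter (0.13). Nuclear genes of oxidative phosphorylation fell, 27 of 71 lower and 2 higher (the same numbers adjusted over the list alone). Their median was −0.10 (camera adjusted p = 0.00713, adjusted p = 0.829 with an estimated correlation), a call that ended without fed 3 h replicate 1 (adjusted p = 0.0509, from 0.000524 over the alternatives). Ndufb2, a complex I subunit, changed by −0.49. The mitochondrial mRNAs had 0 of 7 higher and 0 lower (the same numbers adjusted over the list alone) (median −0.06, camera adjusted p = 0.725, adjusted p = 0.900 with an estimated correlation). Mfn2 (0.17) and Opa1 (0.18) rose, Pink1 fell by 0.31, and Mfn1 (−0.05, adjusted p = 0.416) and Dnm1l (0.02, adjusted p = 0.715) were not called. The integrated stress response list had 11 of 23 higher and 5 lower (12 and 5 adjusted over the list alone) and was not called (median 0.15, camera adjusted p = 0.0547, adjusted p = 0.797 with an estimated correlation), except without unfed replicate 2 (adjusted p = 0.0350) or 3 (0.0401, to 0.0744 over the alternatives).

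Lysosomal genes rose, 16 of 36 higher and 4 lower (the same numbers adjusted over the list alone). Their median was 0.07 (camera adjusted p = 0.0405, adjusted p = 0.829 with an estimated correlation), and the hydrolases Ctsk (0.41), Ctsl (0.40) and Hexa (0.39) were among them. The call ended with the replicate number in the model (adjusted p = 0.0503) and without unfed replicate 2 or 3 or fed 3 h replicate 1 (0.0129 to 0.112 over the alternatives). Engulfment genes had 10 of 25 higher and 8 lower (10 and 9 adjusted over the list alone) and were not called (median −0.07, camera adjusted p = 0.896, adjusted p = 0.914 with an estimated correlation). Axl rose by 0.45 (SE 0.0542), to 1289 ± 54.7 CPM, and Tyro3 by 0.24, Gas6 fell to 53.2 ± 2.14 CPM, a log2 fold change of −1.27, and Mertk was not called (−0.23, adjusted p = 0.643). Immediate early genes had 15 of 28 higher and 9 lower (16 and 9 adjusted over the list alone) and were not called (median 0.24, camera adjusted p = 0.386, adjusted p = 0.829 with an estimated correlation), with Dusp5, a MAP kinase phosphatase (1.04), higher and Egr2, a transcription factor (−1.45), lower. Oxidative stress genes had 10 of 21 higher and 7 lower (12 and 7 adjusted over the list alone) and were not called (median 0.10, camera adjusted p = 0.277, adjusted p = 0.797 with an estimated correlation). Hmox1, the haem-degrading enzyme, rose from 116 ± 2.98 to 306 ± 29.2 CPM, and Txnrd1, a thioredoxin reductase, by 1.28. Hypoxia-inducible genes had a median of 0.06, a mean of −0.06 and a downward test (camera adjusted p = 0.725, adjusted p = 0.829 with an estimated correlation). Vegfa, the endothelial growth factor, rose by 1.39, and Adm, a vasodilator peptide, fell by 0.97. Collagen and matrix genes had 17 of 34 higher and 11 lower (17 and 13 adjusted over the list alone) and were not called (median 0.13, camera adjusted p = 0.277, adjusted p = 0.829 with an estimated correlation). Timp3 (1.81) and Timp1 (1.33), inhibitors of matrix proteases, were higher and Col6a1 (−0.96) was lower.

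**Figure D2:**
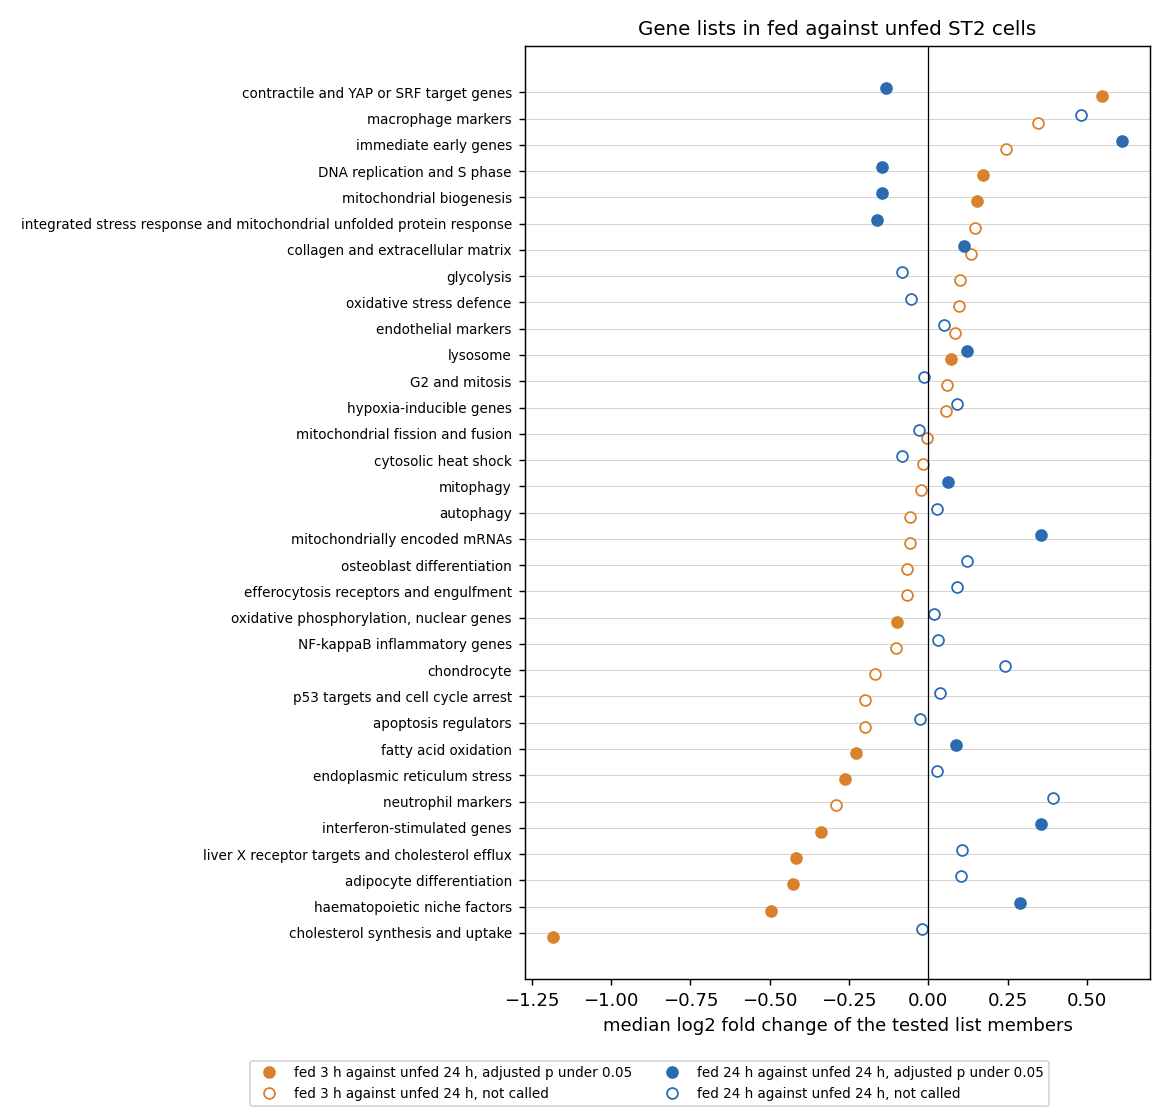
Median log2 fold change (horizontal axis) of the tested members of each of the 33 gene lists in fed 3 h and fed 24 h cells against unfed cells of 24 h, with filled points for lists with a camera adjusted p under 0.05 at the preset correlation and open points for the others. The cholesterol list lies lowest at 3 h (−1.18) and near 0 at 24 h (−0.02), and 0 lists were called with an estimated correlation.

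The change over time among fed cells was read from fed 24 h against fed 3 h cells, which shared the sort for uptake. Fos rose 16.2-fold, from 18.8 ± 10.5 to 304 ± 51.2 CPM (SD, n = 3 each, log2 4.02, SE 0.269, edgeR adjusted p = 4.94e-09). Haptoglobin (Hp, chromosome 8, 109575128 to 109579172) rose from 5.70 ± 0.471 to 85.8 ± 6.61 CPM (log2 3.91, SE 0.148). Ccn2 fell from 3861 ± 421 to 761 ± 46.7 CPM (log2 −2.34, SE 0.0756). Cxcl12 rose by 1.81 (SE 0.0749), Kitl by 1.64 (SE 0.0716), Alpl by 2.82 (SE 0.0976) and Spp1 by 1.07 (SE 0.0561).

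By the edgeR test, 4174 genes were higher and 4091 lower at 24 h than at 3 h. Their median absolute log2 fold change was 0.41, and 756 and 429 reached a log2 fold change of 1. In 65.9% of the genes the libraries did not overlap, against 10% by chance. The other largest rises among the named genes were in Crocc2 (17.1-fold), Kctd12 (3.66), Islr (11.8-fold), Agt, which encodes angiotensinogen (3.05), Mc5r (3.00) and Spry1, an inhibitor of growth factor signalling (2.95). Other large falls were in S100a7a, a calcium-binding protein (−3.11), Sema7a (−2.82), Il1rl1 (−2.42), Klf5 (−2.37), Aif1l (−2.32) and Hmga2, a chromatin protein of proliferating cells (−2.31). Runx2 rose by 0.23, Sp7 by 1.74, Pink1 by 0.55 and Gas6 by 1.92. Axl (−0.64), Tyro3 (−0.40), Tfam (−0.39) and Mfn2 (−0.28) fell. Mfn1 (0.01, adjusted p = 0.867), Opa1 (−0.04, adjusted p = 0.424) and Dnm1l (0.06, adjusted p = 0.201) were not called, but Dnm1l was with the stricter filter (0.09). The call of Col1a1 (−0.13) ended without unfed replicate 3, any fed 3 h replicate or fed 24 h replicate 1 or 3 (values −0.14 to −0.09), with no filter or a stricter filter and with the replicate number in the model (adjusted p from 0.00470 to 0.158 over the alternatives). That of Mertk (0.91) ended without fed 3 h replicate 1 or 3 or fed 24 h replicate 3 (values 0.57 to 0.84).

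The cholesterol list rose, 24 of 24 higher and 0 lower (the same numbers adjusted over the list alone). Its median was 1.06 (camera adjusted p = 3.73e-13, adjusted p = 0.300 with an estimated correlation), and Fdps (1.97) and Mvd (1.75), enzymes of isoprenoid synthesis, were among the rises. Interferon-stimulated genes rose, 23 of 31 higher and 0 lower (the same numbers adjusted over the list alone). Their median was 0.73 (camera adjusted p = 5.28e-06, adjusted p = 0.445 with an estimated correlation). The niche factors had 14 of 17 higher and 2 lower (the same numbers adjusted over the list alone) and a median of 0.60 (camera adjusted p = 8.29e-05, adjusted p = 0.300 with an estimated correlation). Fatty acid oxidation rose, 21 of 25 higher and 2 lower (the same numbers adjusted over the list alone). Its median was 0.29 (camera adjusted p = 0.000149, adjusted p = 0.445 with an estimated correlation). Endoplasmic reticulum stress genes rose, 17 of 21 higher and 2 lower (the same numbers adjusted over the list alone). Their median was 0.28 (camera adjusted p = 0.000410, adjusted p = 0.300 with an estimated correlation). Liver X receptor targets rose, 10 of 13 higher and 1 lower (the same numbers adjusted over the list alone). Their median was 0.77 (camera adjusted p = 0.00718, adjusted p = 0.445 with an estimated correlation). Adipocyte genes rose, 12 of 18 higher and 4 lower (the same numbers adjusted over the list alone). Their median was 0.58 (camera adjusted p = 0.0140, adjusted p = 0.300 with an estimated correlation). Bnip3, a mitophagy receptor, rose by 1.08, and Pdk1, a kinase that limits pyruvate oxidation, by 1.54.

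S phase genes fell, 25 of 30 lower and 0 higher (the same numbers adjusted over the list alone). Their median was −0.29 (camera adjusted p = 8.64e-07, adjusted p = 0.445 with an estimated correlation). Contractile genes fell, 19 of 21 lower and 1 higher (19 and 2 adjusted over the list alone). Their median was −0.55 (camera adjusted p = 8.08e-07, adjusted p = 0.455 with an estimated correlation), with Ankrd1 (−1.75) and Cnn1, the smooth muscle calponin (−1.19), among them. Mitochondrial biogenesis fell, 14 of 18 lower and 0 higher (15 and 0 adjusted over the list alone). Its median was −0.34 (camera adjusted p = 0.000130, adjusted p = 0.445 with an estimated correlation), and Twnk changed by −0.65. The integrated stress response list fell, 16 of 23 lower and 3 higher (16 and 4 adjusted over the list alone). Its median was −0.34 (camera adjusted p = 0.00593, adjusted p = 0.455 with an estimated correlation). Nuclear genes of oxidative phosphorylation rose, 35 of 71 higher and 7 lower (the same numbers adjusted over the list alone). Their median was 0.15 (camera adjusted p = 0.0124, adjusted p = 0.693 with an estimated correlation), a call that ended without fed 24 h replicate 2 (adjusted p = 0.0664, from 0.00114 over the alternatives). Immediate early genes had 17 of 28 higher and 8 lower (the same numbers adjusted over the list alone) and were not called (median 0.59, camera adjusted p = 0.0978, adjusted p = 0.599 with an estimated correlation). The mitochondrial mRNAs had 6 of 7 higher and 0 lower (7 and 0 adjusted over the list alone) and were not called (median 0.43, camera adjusted p = 0.0978, adjusted p = 0.599 with an estimated correlation).

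The comparisons of fed 3 h and of fed 24 h cells with unfed cells shared the same 3 unfed libraries. Of the genes called in both, 440 were higher in both, 384 lower in both and 1716 in opposite directions, the last including Ccn2, Alpl, Cxcl12 and Kitl. Simulated groups without any change gave means of 0.1, 0.1 and 0, which is fixed near 0 because almost no gene is called in them. Independent lists of the same lengths would share 507, 551 and 1057. Real but unrelated changes against shared unfed libraries were not simulated. Across the tested genes, which are not independent replicates, the log2 fold changes had a correlation of −0.133 against a mean of 0.513 in the simulations. Their covariance was −0.0234, against 0.0171. It was −0.00302 without unfed replicate 2 and −0.00186 without unfed replicate 3. The 3 unfed libraries are too few to be divided between the comparisons. The number lower in both was 218 without fed 24 h replicate 1 and 238 without fed 24 h replicate 3, and the number in opposite directions was 1135 without unfed replicate 3.

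**Figure D3:**
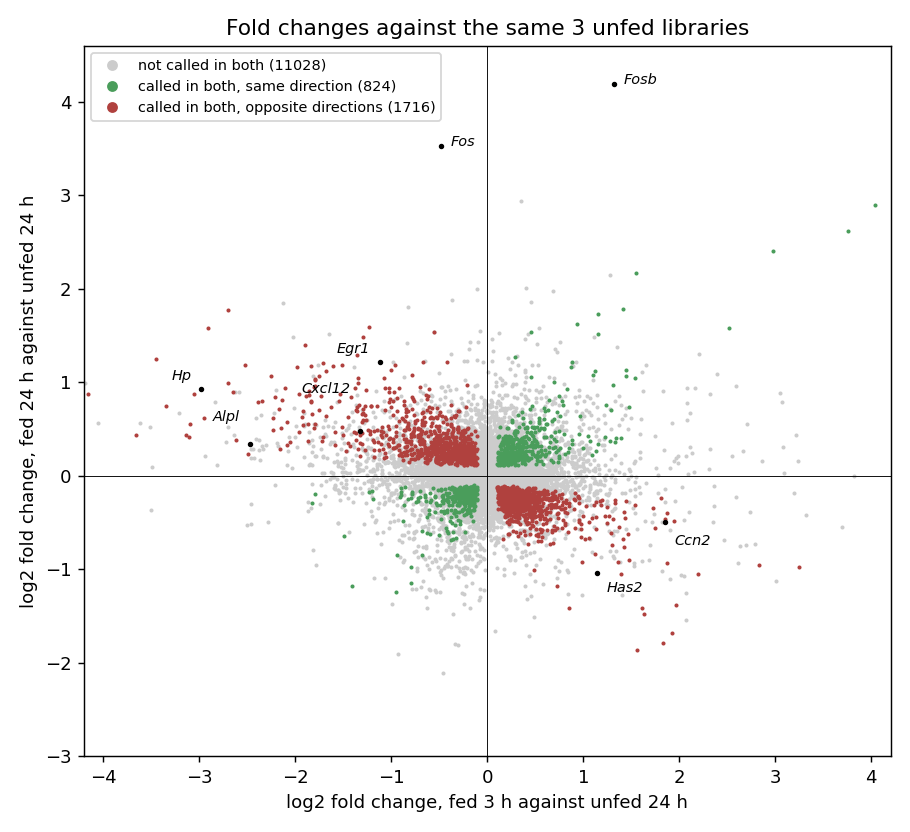
Log2 fold change of each tested gene in fed 24 h against unfed cells (vertical axis) and in fed 3 h against the same unfed cells (horizontal axis), coloured by whether it was called in both in the same direction (824), in both in opposite directions (1716) or not in both (11028), with 13 genes outside the plotted range. Of the genes called in both, most lie in the upper left and lower right quadrants, where Alpl, Cxcl12, Hp and Ccn2 are marked.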

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

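The tests of shared libraries, gene trends and time in culture were chosen only after the results were seen. The gene and list differences were tested by the comparison of fed 24 h with fed 3 h cells, planned before the data were examined. Values are log2, fed 24 h minus fed 3 h. Of 50 genes named by size of change or in the fixed set, 31 were called in opposite directions against unfed cells. These 31 also differed between the fed groups. Over all 13568 tested genes, 1716 were called in opposite directions. Opposite calls against the same unfed libraries nearly fix a difference between the fed groups, so that difference is no separate support. Many of the 50 were named for a large change in these same comparisons, so their share does not extend to other genes.

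Those higher at 24 h included the niche factors Cxcl12 (1.81) and Kitl (1.64), the osteoblast genes Alpl (2.82), Sp7 (1.74) and Spp1 (1.07), the mitophagy kinase Pink1 (0.55) and the early gene Nr4a1 (2.09). The others higher at 24 h were Crocc2 (4.09), Hp (3.91), Kctd12 (3.66), Islr (3.56), Agt (3.05), Mc5r (3.00), Spry1 (2.95), Colec10 (2.73) and Il1rn (2.72). Those lower at 24 h included the engulfment receptor Axl (−0.64), the fusion gene Mfn2 (−0.28), Tfam, which packages mitochondrial DNA (−0.39), and the matrix regulators Ccn2 (−2.34), Has2 (−2.19) and Ccn4 (−1.16). The others lower at 24 h were S100a7a (−3.11), Il1rl1 (−2.42), Klf5 (−2.37), Aif1l (−2.32), Hmga2 (−2.31), Nipal1 (−2.27), Hmga1b (−1.70), Pik3cb (−1.22) and Cdca7 (−0.84). For some of the fixed set, a call against unfed cells ended when single libraries were left out, as given above. This held at 24 h for Mfn2 (7 libraries), Sp7 (4) and Axl (3), and at 3 h for Tfam (3). The opposite directions of these genes are therefore uncertain. Of the lists, niche factors (0.60), interferon-stimulated genes (0.73) and fatty acid oxidation (0.29) were higher in the median, and mitochondrial biogenesis (−0.34), S phase (−0.29) and contractile genes (−0.55) were lower. With an estimated correlation, 0 of these lists were called between the fed groups (adjusted p from 0.300 to 0.455).

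The opposite directions were weighed as a pattern over the tested genes. Shared unfed libraries push fold changes towards the same sign, so the covariance says nothing further about them: with a prior count of 2 it was −0.0246, against 0.0127 to 0.0150 in 20 simulations without change, and −0.00639 without unfed replicate 2 and −0.0136 without unfed replicate 3. With trends on gene length, GC content and expression removed it was −0.0229, and −0.00555 and −0.0120 without these libraries, which argues against these trends as the whole cause. Time in culture may contribute: 0 unfed libraries were collected at 3 h, so at 3 h feeding and time in culture cannot be told apart. An early response to feeding that later turns remains an untested hypothesis.

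Among 63 marker genes with too few counts for the edgeR test, Hba-a1, a subunit of haemoglobin, had 20 counts in all fed 3 h libraries, 3 in all unfed and 4 in all fed 24 h libraries (3 h against unfed, exact conditional test of counts, adjusted p = 0.0348 over 64 tests). This p covers counting error only, not the spread between libraries. A count was seen in 3 of the 3 fed 3 h libraries. A near-identical copy, Hba-a2, makes the count uncertain, and no explanation was tested.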

How the results depend on the processing

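The fit without the genes linked to ribosomal RNA was chosen only after the data were seen. A minimum log2 fold change of 1 left 103 higher and 47 lower genes in fed 24 h and 305 and 410 in fed 3 h against unfed cells, and 756 and 429 between the fed groups, fewer because most changes were small. With an estimated correlation, camera called 0 lists higher and 0 lower in each comparison. By fry, which does not compare a list with other genes, 13 lists were higher and 6 lower at 24 h and 8 and 12 at 3 h against unfed cells, and 18 were higher and 8 lower between the fed groups. Lists that fry but not camera called at 24 h included engulfment (higher, fry adjusted p = 0.00680), fission and fusion (lower, 0.00748) and neutrophil markers (higher, 0.0452). Conversely, fry did not call the mitochondrial mRNAs (adjusted p = 0.0670) or the contractile list (0.105) at 24 h, which camera called. The same held at 3 h for nuclear genes of oxidative phosphorylation (fry adjusted p = 0.0765).

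Leaving out each library gave 1426 to 2241 lower genes at 24 h against unfed cells, the lowest without fed 24 h replicate 1, and 5 to 9 higher lists, the lowest without unfed or fed 24 h replicate 2. Genes lower in both comparisons with unfed cells numbered 218 to 387, the lowest without fed 24 h replicate 1, and those in opposite directions 1135 to 1861, the lowest without unfed replicate 3. The cause was not tested. Over these fits, named genes gave 4171 results on the same side of the threshold, 160 calls lost and 2 gained.

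With the replicate block, 3911, 6669 and 8091 genes were called in fed 24 h and fed 3 h against unfed and between the fed groups, of which 3845, 6609 and 8022 were also called without it. The labels do not say that the numbers pair the libraries: correlations of residuals ran from −0.163 to 0.0578 for the same number and from −0.0971 to 0.104 for others. No call of a named gene or list changed direction among the alternatives, but uncalled values did: 5 of genes and 7 of lists with a library left out, 2 of genes by limma-voom, 1 of genes with the stricter filter and 1 of lists by fry. The alternatives on human genes were not run, because the table holds none. Low counts limited Bglap, Ppargc1a and Mertk.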

Other observations

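The 7 further lists, the genes named from them and all tests of patterns here were chosen only after the data were seen, and only the splits of the libraries were planned before. Genes of ribosome biogenesis, which build ribosomes in the nucleolus, rose at 3 h against unfed cells, 47 of 50 higher and 0 lower (the same numbers adjusted over the list alone). Their median was 0.50 (camera adjusted p = 5.15e-14, adjusted p = 0.370 with an estimated correlation), with the nucleolar proteins Gnl3 (0.95) and Ncl (0.74) among them. At 24 h they fell, 42 of 50 lower and 0 higher (the same numbers adjusted over the list alone). The median was −0.28 (camera adjusted p = 7.96e-13, adjusted p = 0.487 with an estimated correlation), and Polr1b, a subunit of RNA polymerase I, changed by −0.66. Between fed 24 h and fed 3 h cells it was −0.84 (camera adjusted p = 1.25e-16, adjusted p = 0.412 with an estimated correlation). Aminoacyl-tRNA synthetases and amino acid transporters moved likewise, with 17 of 28 higher and 2 lower (18 and 2 adjusted over the list alone) and a median of 0.14 at 3 h (camera adjusted p = 0.00520, adjusted p = 0.701 with an estimated correlation). At 24 h they had 16 of 28 lower and 1 higher (19 and 2 adjusted over the list alone) and a median of −0.15 (camera adjusted p = 7.56e-06, adjusted p = 0.487 with an estimated correlation). Slc7a5, a leucine transporter, changed by 0.53 at 3 h and −0.65 at 24 h against unfed cells. Cytosolic ribosomal proteins had 24 of 74 lower and 1 higher (16 and 1 adjusted over the list alone) and a median of −0.10 at 3 h (camera adjusted p = 0.00820, adjusted p = 0.820 with an estimated correlation). At 24 h they had 22 of 74 lower and 0 higher (20 and 0 adjusted over the list alone) and a median of −0.09 (camera adjusted p = 7.56e-06, adjusted p = 0.524 with an estimated correlation), and many have near-identical pseudogenes, so their counts are uncertain. Mitochondrial ribosomal proteins had 20 of 74 lower and 1 higher (19 and 1 adjusted over the list alone) at 24 h, so most were not called (median −0.08, camera adjusted p = 9.45e-05, adjusted p = 0.524 with an estimated correlation). Proteasome subunits had 11 of 37 lower and 2 higher (the same numbers adjusted over the list alone) (median −0.06, camera adjusted p = 0.0279, adjusted p = 0.604 with an estimated correlation), and fry did not call them (adjusted p = 0.157). Nor did fry call cytosolic ribosomal proteins at 3 h (adjusted p = 0.177) or 24 h (0.0980), or mitochondrial ribosomal proteins at 24 h (0.0605). The 7 further lists were not tested with libraries left out.

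Complement and acute phase genes, many of them innate immune proteins secreted by stromal cells, moved the other way. They fell at 3 h, 17 of 20 lower and 0 higher (17 and 1 adjusted over the list alone). Their median was −1.41 (camera adjusted p = 3.92e-07, adjusted p = 0.370 with an estimated correlation), and Lbp, which binds bacterial lipopolysaccharide, changed by −2.39. At 24 h they rose, 16 of 20 higher and 1 lower (17 and 1 adjusted over the list alone). The median was 0.67 (camera adjusted p = 2.33e-08, adjusted p = 0.487 with an estimated correlation), with C1s1, a complement protease, at 0.94. The list was chosen after the data were seen and holds Hp, Agt, Il1rn and Colec10, which had already been named. Its p-values are therefore no separate support. Target genes of transforming growth factor beta rose at 3 h, 16 of 28 higher and 7 lower (17 and 7 adjusted over the list alone). Their median was 0.47 (camera adjusted p = 0.00128, adjusted p = 0.370 with an estimated correlation). At 24 h the median was 0.04, the mean −0.03 and the test upward (camera adjusted p = 0.746, adjusted p = 0.885 with an estimated correlation). This list includes Ccn2, Tnc, Adamts6 and Hmga2, also named before, so the same limit holds for its p-values. Lists of erythroid and platelet and of lymphocyte markers had too few tested members, with 632, 667 and 877 and 14, 7 and 6 counts in all unfed, fed 3 h and fed 24 h libraries.

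Immediate early genes, which also respond to handling, were higher in fed 24 h than in unfed cells in 18 of 28 cases and lower in 4 (adjusted p = 0.465 with an estimated correlation). The sort common to both fed groups could contribute: at 3 h the 18 members that rose at 24 h had a median of −0.41 (SD 0.85), with 6 higher and 9 lower, but all 28 tested members had 0.24 (SD 0.81), against 0.61 at 24 h. Human RNA counted on mouse genes stays open too: the 26 neutrophil markers together rose by 1.57 CPM and Fos by 278 CPM, but how readily human reads count on each mouse gene was not measured. RNA quality or handling of the fed 24 h libraries could contribute: Fos was at 18.1 CPM in the fed 3 h library with a raised share of ribosomal RNA linked reads, and a single library excludes nothing. A lasting signal from ingested neutrophils was not tested apart from it.

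All members of the cholesterol list were lower in fed 3 h cells. With trends on gene length, GC content and expression removed, the median was −1.21 (SD 0.39, highest member −0.42), which argues against a trend. Sterol taken up with the neutrophils may lower these genes and would be predicted to raise liver X receptor targets. The median of that list was −0.42 against unfed cells of another time. This stays open, because time differed too and the list also holds other genes, such as the receptors themselves and Soat1. Time in culture may contribute too, since 0 unfed libraries were collected at 3 h, and it cannot be told apart from feeding.

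Each comparison of 3 with 3 libraries allows 10 splits, too few for a share under 0.05. In fits of the 6 libraries compared, the real splits gave 3915, 6661 and 8394 genes for fed 24 h and fed 3 h against unfed and for fed 24 h against fed 3 h cells, and the highest other splits gave 1, 1 and 1. Splits with as many genes, the real one included, numbered 1, 1 and 1. Every other split mixes the groups, so that a difference between them widens the spread within each. Few gene calls in those splits are therefore built in and give no chance level. For lists called by camera at the preset correlation, the real splits gave 11, 11 and 12, the highest other splits 14, 9 and 10, and splits with as many numbered 4, 1 and 1. At 24 h against unfed cells, the number of lists called therefore does not set the real groups apart from mixed ones.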
